A study of Mus musculus with 7 samples.

How the data were processed

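Polyadenylated RNA of embryoid bodies on day 4 was measured in 7 libraries made with the Lexogen QuantSeq 3′ kit, which reads transcripts from their 3′ end, per the labels' protocols. Cells were freed of feeder fibroblasts by a short incubation on gelatin and seeded as hanging drops of 500 cells in 27 µl, per the labels. Samples were grouped by title into WT (2 libraries), pKO (2), pInv (1), Ctrl (1) and KD (1), because the titles carry the replicate numbers. The genotype field names other genotypes for 5 of the 7, and grouping by that field was an alternative. The series' design text and the sample field also name the knockdown differently (Cas9 and dCas9).

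For each library the authors deposited a table of RSEM estimates per gene, holding expected counts, TPM and FPKM per the file headers. Reads were handled with RSEM on the mouse build mm9, per the submitters' processing notes, which give no version. The expected counts were deposited without normalization, and were rounded to whole numbers here before any test. The TPM values, scaled by the authors to transcript length and to a fixed total per library, served in 1 alternative. The FPKM values deposited by the authors were not used in any test. Trimming, strand setting and the handling of duplicate reads are not given in the sources used here. Without strand, a gene cannot be told from an overlapping neighbour, and 3′ reads of near-identical genes are split by the estimate.

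The tables hold 24990 features named by NCBI gene number. Names were taken from a RefSeq gene table of GRCm38, a later build than that of the files, so it was used for names and for which genes neighbour each other, and no coordinates are given. It named 23447 features as single genes, 375 as merged genes and 1142 as further copies of a transcript, and 26 stayed unnamed. Of the gene list entries, 760 matched a single feature, 13 a merged one and 19 none. The 45S ribosomal RNA precursor took 12.9% to 24.1% of the expected counts of a library. Totals were 2564478 (WT1), 1898350 (WT2), 2125965 (pKO1), 2400373 (pKO2), 2260792 (pInv), 2034596 (Ctrl) and 2059522 (KD).

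Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which kept 10265, and libraries were scaled by TMM. All 7 libraries entered 1 quasi-likelihood fit with a coefficient per group and no covariate. Only WT and pKO have 2 libraries, so the spread rests on 2 residual degrees of freedom and a moderated prior of 5.86, with a common biological coefficient of variation of 0.294. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 ratios used a prior count of 2. KD and Ctrl have 1 library each, so genes at 20 CPM (counts scaled by library size) or more in either were called by size, at a 2-fold ratio or more, without a p-value. Ratios of 2 libraries carry exact binomial 95% intervals, and a ratio to 0 counts is given as a lower bound from a floor of 3 counts.

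Before the data were examined, the tests, the alternatives, 31 gene lists of cell types and pathways and the rule for named genes were fixed. Lists with 5 or more tested genes (26) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. For KD against Ctrl each list's median was placed among 10000 random lists matched on mean expression in 20 bins. Too few genes were tested of the trophoblast (3), 2-cell-like (1), HOX (4), Y-linked (3) and mitochondrial (0) lists. The rule named Eomes first, then the 10 largest changes each way among called genes at a mean of 5 CPM or more (5 each way for pInv against pKO), and the 5 smallest p where none was called. For KD against Ctrl it took the 10 largest ratios each way, and for each list described up to 4 members with the smallest adjusted p or, for KD, the largest ratio. T, Mixl1, Foxa2, Pou5f1, Eef1a1 and the macrophage genes beyond that rule were chosen after their values were seen.

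The steps were tested on simulated counts with the real means and library sizes and 200 genes changed. For pKO against WT, 4% of genes changed 2-fold passed, 64% of those changed 4-fold and 90% of those changed 16-fold, among 9857 genes. For pInv against WT these shares were 2%, 32% and 80% among 9832, and for pInv against pKO 6%, 38% and 84% among 9882. For KD against Ctrl, the size rule took 48.3% of genes changed 2-fold and 96.8% of those changed 4-fold, and also 512 unchanged genes among the 5081 in the step. The simulated spread was estimated from WT and pKO. Noise was drawn independently for each gene and library. In the real data the WT1 to WT2 and pKO1 to pKO2 differences correlated across genes (0.496), which the simulation did not include. For pKO against WT, 106 real genes had an unadjusted p under 0.05 in edgeR's test, where chance would give 513. The shares passing in the tested comparisons can therefore overstate what would be called in the real data. The real pair of KD and Ctrl gave 255 genes in all, so 512 overstates the rule's false calls for it. The tests gave 9, 8 and 11 false calls in the 3 tested comparisons.

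Alternatives were DESeq2 size factors, upper quartile scaling, no filter, a stricter filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), only WT, pKO and pInv in the fit, each WT and pKO library left out, the genotype field, and the replicate number as a block. For KD they were prior counts of 0.5 and 5 and minima of 10 and 50 CPM. Other scalings moved the median of all genes by at most 0.03 on the log2 scale. Fits without the 45S feature, KD against WT1 in place of Ctrl, Ctrl against WT for the gene lists, and KD without 30 macrophage genes were chosen after seeing the data.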

Results

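The data were 3′ RNA-seq libraries of mouse embryoid bodies, the aggregates that embryonic stem cells form when they differentiate in suspension, made from the R1 embryonic stem cell line and collected on day 4. The perturbed locus was Meteor, a long non-coding RNA gene that the study's title ties to the level of Eomes, a T-box transcription factor of the primitive streak. By title, 2 libraries came from wild-type cells (WT1 and WT2), 2 from cells lacking the Meteor promoter (pKO1 and pKO2), 1 from cells with the promoter inverted (pInv), 1 from an empty-vector control (Ctrl) and 1 from a CRISPR knockdown of Meteor (KD). The genotype field of the labels contradicts the titles of 5 of the 7 libraries. It gives the promoter knockout for both libraries titled WT, the promoter inversion for the first library titled pKO, and wild type for the second library titled pKO and for the library titled pInv. Groups below follow the titles, and every direction drawn from them depends on that choice. Totals ran from 1898350 expected counts in WT2 to 2564478 in WT1, of which 24.1% and 17.4% fell on the 45S ribosomal RNA precursor. Levels are given as CPM, counts scaled by library size and TMM factor. A count of 0 allowed a level of up to 1.12 CPM in WT1 and 1.80 in WT2. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, technical spread included. No molecular identifiers are named in the sources used here, so intervals and floors cover counting error only.

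The level of Eomes (NCBI gene 13813) did not separate the groups. It stood at 459 CPM in WT1, 312 in WT2, 337 in pKO1, 445 in pKO2, 390.0 in pInv, 421 in Ctrl and 399 in KD. The means were 385 ± 104 CPM in WT (SD, n = 2) and 391 ± 76.0 CPM in pKO (SD, n = 2). The log2 difference was 0.02 (SE 0.30) for pKO against WT, 0.02 (SE 0.37) for pInv against WT and 0.00 (SE 0.37) for pInv against pKO, each with an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The KD to Ctrl ratio of Eomes was 0.948, with an exact 95% counting interval from 0.861 to 1.04. The Meteor transcript was not analysed here because no feature was matched to it by name, so the targeted gene does not check the titles. The noncoding gene 4933432G23Rik (NCBI gene 71196), the next one listed upstream of Eomes in the reference and chosen after its values were seen, had 85.1 CPM in WT1, 167 in WT2, 102 in pKO1, 133 in pKO2, 84.0 in pInv, 101 in Ctrl and 104 in KD. The Eomes locus list, which holds Eomes itself and genes near it, had 13 tested genes. None of the 13 passed the threshold in edgeR's test in any of the 3 tested comparisons. Their list had a median log2 difference of −0.10 for pKO against WT, −0.46 for pInv against WT (9 of 13 lower) and −0.18 for pInv against pKO (10 lower), with camera adjusted p of 0.927, 0.381 and 0.176. Azi2 was at 15.3 CPM in pInv against 21.7 and 29.4 in WT, and Oxsr1 at 18.7 against 23.2 and 28.2. For KD against Ctrl the median was 0.13 (percentile 61.83 of random lists).

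**Figure D1:**
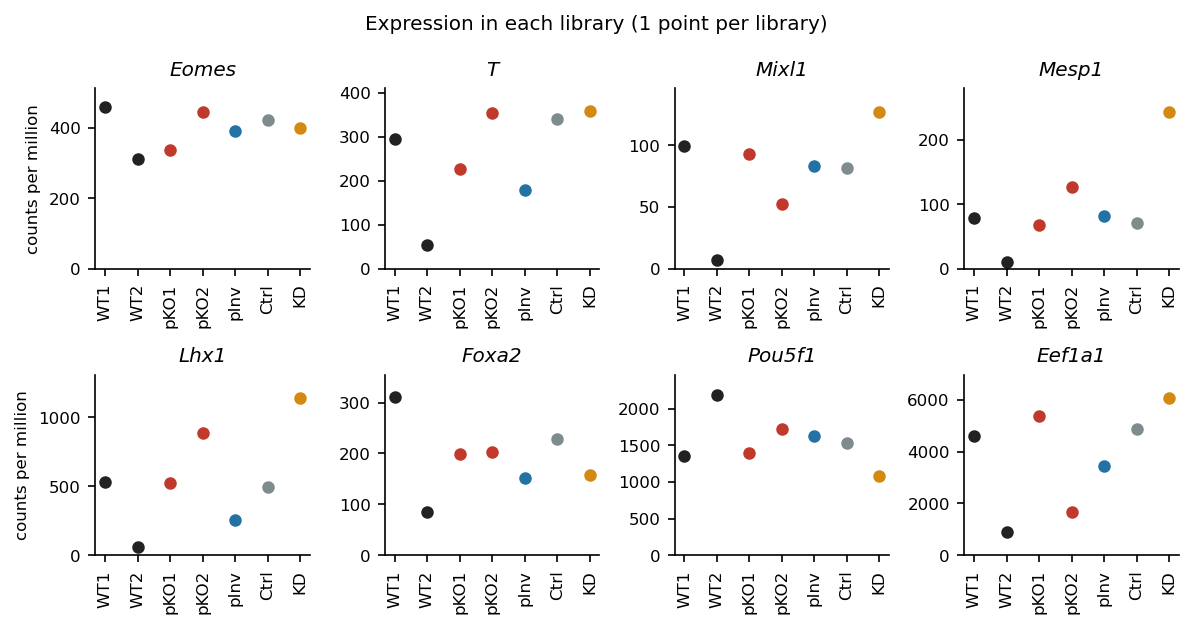
Level of 8 genes in each library, in CPM on linear axes that start at 0, with 1 point per library and the libraries named by title. Eomes lay between 312 and 459 CPM, while T, Mixl1, Mesp1, Lhx1 and Foxa2 were lowest in the WT2 library and Mesp1 and Lhx1 highest in the KD library.

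The library titled WT2 stood apart from the rest in genes of the primitive streak, the site where mesoderm and endoderm arise. It held 54.6 CPM of T against 294 in WT1, 7.20 CPM of Mixl1 against 99.0, 10.8 CPM of Mesp1 against 79.1 and 58.2 CPM of Lhx1 against 531.5. The endoderm factor Foxa2 stood at 84.6 CPM in WT2 and 311 in WT1, while the pluripotency factor Pou5f1 stood at 2188 and 1359. The translation factor Eef1a1 was at 887 CPM in WT2 and 1663 in pKO2, against 3452 to 6093 in the other 5 libraries. Of 4682 genes at 20 CPM or more on average, 434 lay 2-fold or more below the median of the other libraries in WT2 and 120 above it. In pKO2 these counts were 95 and 17, and in WT1 they were 13 and 9. The SD of the log2 ratios to that median was 0.697 in WT2 and 0.285 to 0.408 in the other libraries.

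The comparison of pKO with WT asks what loss of the Meteor promoter does to day 4 embryoid bodies. Genes of hypoxia and glycolysis fell as a group in the libraries titled pKO relative to those titled WT, with 26 of 28 tested members lower and a median log2 difference of −0.44 (limma's camera, adjusted p = 1.11e-05; adjusted p = 0.515 with an estimated correlation). The empty-vector control stood as low, with 25 of 28 members lower in Ctrl than in WT and a median of −0.45 (camera, adjusted p = 2.89e-05, and adjusted p = 0.57 with an estimated correlation), so under the titles the list sets the WT libraries apart from the control as well as from pKO. The oxygen sensor Egln3 was at 30.7 and 39.0 CPM in WT and 11.5 and 16.4 in pKO, the hexokinase Hk1 at 18.0 and 28.8 against 8.60 and 9.85, and Gapdh at 1562 and 1528 against 936 and 1055. Aldoc, a glycolytic aldolase, had 40.1 and 82.8 CPM in WT and 32.0 and 19.7 in pKO. The extraembryonic endoderm list rose, with 16 of 19 members higher and a median of 0.44 (camera, adjusted p = 0.000123, and adjusted p = 0.515 with an estimated correlation), among them the basement membrane collagen Col4a1 at 6.75 and 6.0 CPM in WT and 9.55 and 15.6 in pKO. Nascent and paraxial mesoderm (15 of 19 members higher, median 0.32, camera adjusted p = 0.000494, and adjusted p = 0.559 with an estimated correlation) and the epithelial-mesenchymal transition list (10 of 11, median 0.56, camera adjusted p = 0.00088, and adjusted p = 0.543 with an estimated correlation) rose as well. Ctrl stood well above WT2 but not WT1 in these lists, with medians of 1.42 over WT2 and −0.25 over WT1 for nascent mesoderm, 0.71 and 0.04 for extraembryonic endoderm, and 0.88 and 0.12 for the transition list. Over both WT libraries the transition list was higher in Ctrl (median 0.45, camera adjusted p = 0.037, and adjusted p = 0.57 with an estimated correlation). In the transition list, fibronectin (Fn1) had 125 and 31.8 CPM in WT and 173 and 269.6 in pKO, and vimentin (Vim) 20.99 and 12.0 against 26.3 and 31.2. The pluripotency list rose with 14 of 19 members higher and a median of 0.17 (camera, adjusted p = 0.00788, and adjusted p = 0.515 with an estimated correlation), led by Fbxo15 at 6.75 and 4.80 CPM in WT and 12.9 and 13.1 in pKO.

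In all, 11 of 26 lists passed camera's threshold for pKO against WT, 10 of them higher, and with an estimated correlation 0 passed (smallest adjusted p = 0.515). By fry, 1 list passed, the pluripotency list (adjusted p = 0.0403). In Ctrl that list had a median of 0.09 over both WT libraries, 0.31 over WT1 and 0.07 over WT2. Without WT2, 3 lists passed camera, namely pluripotency, extraembryonic endoderm and hypoxia and glycolysis (adjusted p = 0.00395, 0.00395 and 8.22e-07). Without pKO2, 2 passed, the latter pair (camera, adjusted p = 0.00397 and 0.00029). Without WT1, pluripotency (camera, adjusted p = 0.317) and post-implantation epiblast (0.254) did not pass. Camera's other lists higher in pKO were neuroectoderm (median 0.52, adjusted p = 0.00409, and adjusted p = 0.515 with an estimated correlation) and definitive endoderm (0.20, adjusted p = 0.00475, and adjusted p = 0.559 with an estimated correlation). Lateral plate and cardiac mesoderm (0.39) and BMP targets (0.86) each had a camera adjusted p of 0.0136, and adjusted p = 0.533 with an estimated correlation. Primitive streak (0.14) and post-implantation epiblast (0.15) each had a camera adjusted p of 0.0373, and adjusted p = 0.642 and adjusted p = 0.533 with an estimated correlation. Ctrl, 1 library, also stood above WT in neuroectoderm (median 0.30), definitive endoderm (0.31) and lateral plate (0.31). It did so too for BMP targets (0.16), primitive streak (0.30) and epiblast (0.23), so levels above WT were not particular to pKO. Without WT2, the primitive streak list turned lower in pKO (camera, adjusted p = 0.421), and nascent mesoderm (0.878), definitive endoderm (0.878), lateral plate (0.37), BMP targets (0.257), neuroectoderm (0.115), epiblast (0.0723) and the epithelial-mesenchymal transition list (0.0723) did not pass. With groups from the genotype field, the hypoxia list was higher in the libraries labelled knockout (camera, adjusted p = 1.18e-05).

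No single gene passed the threshold for pKO against WT among the 10265 tested in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over all genes or adjusted over the list alone, and DESeq2, limma-voom and limma on log2(TPM + 1) also gave 0. At an unadjusted p under 0.05 there were 106 genes, against 513 that chance would give. The 5 genes with the smallest p were higher in pKO. Rian, an imprinted noncoding RNA, was at 118 and 106 CPM in WT and 246 and 208 in pKO, a log2 difference of 1.02 (SE 0.26). Ahnak, a large scaffold protein, had 3.75 and 3.60 CPM in WT and 15.3 and 11.1 in pKO (1.82, SE 0.46), and Spink1, a trypsin inhibitor of endoderm, 4.50 and 3.0 against 13.4 and 11.9 (1.70, SE 0.48). Spin2d had 42.4 and 41.4 CPM in WT and 123 and 99.3 in pKO (1.41, SE 0.28), and the uncharacterised 2210408I21Rik 20.6 and 12.0 against 56.9 and 58.3 (1.79, SE 0.36). Spin2d has close relatives whose reads the counting could split, so its value is uncertain. Ctrl, which shares no library with this comparison, had 187 CPM of Rian, 116 of Spin2d and 17.3 of Ahnak. With pKO1 left out 4 genes passed, and with pKO2 left out 7 did.

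**Figure D2:**
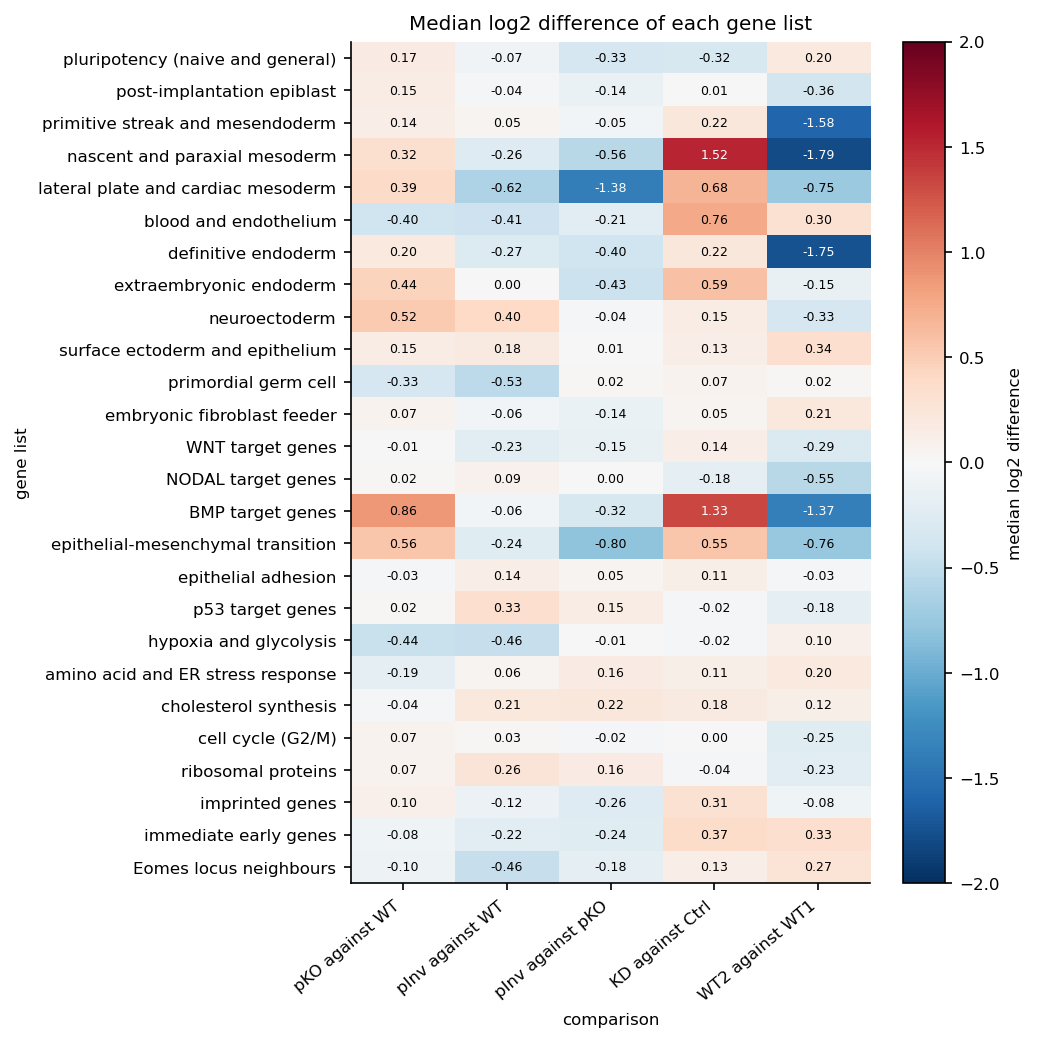
Median log2 difference of each of 26 gene lists (vertical axis) in 4 comparisons and between the 2 libraries titled WT (horizontal axis), with color from −2 to 2 and the value printed in each cell. The nascent and paraxial mesoderm list had a median of 1.52 for KD against Ctrl and of −1.79 for WT2 against WT1.

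The comparison of pInv with WT asks the same of the inverted promoter. Hypoxia and glycolysis genes were lower in pInv than in WT, with 25 of 28 members lower and a median log2 difference of −0.46 (camera, adjusted p = 0.000597, and adjusted p = 0.867 with an estimated correlation). As Ctrl and KD were lower than WT1 by similar medians (−0.44 and −0.41), and pInv and pKO parted evenly (14 of 28 members each way), this shift too lies between the shared WT libraries and all others. The hypoxia-induced oxidase Ero1a was at 10.6 CPM in pInv against 16.9 and 34.8 in WT, the mitophagy receptor Bnip3 at 31.8 against 80.2 and 47.4, and Vegfa at 2.55 against 6.37 and 8.40. Ribosomal protein genes rose, with 47 of 59 higher and a median of 0.26 (camera, adjusted p = 0.000597, and adjusted p = 0.867 with an estimated correlation), among them Rplp2 at 4570.0 CPM against 2916 and 2717. They were also higher in Ctrl than in WT (median 0.18, camera adjusted p = 0.032, and adjusted p = 0.57 with an estimated correlation), by 0.33 over WT2 and 0.06 over WT1. Targets of p53 rose with 16 of 21 higher and a median of 0.33 (camera, adjusted p = 0.0242, and adjusted p = 0.867 with an estimated correlation), with Mdm2, the p53 ubiquitin ligase, at 137 CPM in pInv and 78.7 and 51.0 in WT. By fry no list passed (smallest adjusted p = 0.338). Without WT1, camera's adjusted p was 0.081 for the hypoxia list and 0.228 for p53 targets, and without WT2 it was 0.0546 for the ribosomal protein genes. The nascent and paraxial mesoderm list was higher in pInv without WT1 (camera, adjusted p = 0.00426) and lower without WT2 (adjusted p = 0.0157), so its direction turned with the WT library used.

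No gene passed for pInv against WT in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 152 of 10265 had an unadjusted p under 0.05; DESeq2, limma-voom and limma on log2(TPM + 1) gave 0. C7, a complement component, was at 15.3 CPM in pInv against 1.87 and 3.60 in WT (log2 difference 2.52, SE 0.64), and the germ cell gene Tex15 at 32.7 against 9.00 and 13.2 (1.57, SE 0.43). Cox4i2, a cytochrome c oxidase subunit, had 0 counts in pInv, which allows up to 1.27 CPM, against 4.50 and 7.20 CPM in WT. A further copy of Srp54c was at 0.42 CPM against 14.2 and 9.60, and Spin2d at 95.5 against 42.4 and 41.4, both uncertain because such rows share reads with near-identical genes. The library titled pInv is single and was assumed to vary like those of WT and pKO.

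Between pInv and pKO, the epithelial-mesenchymal transition list was lower in pInv in 10 of 11 members, with a median log2 difference of −0.80 (camera, adjusted p = 0.0212, and adjusted p = 0.618 with an estimated correlation). Vim was at 15.3 CPM in pInv against 26.3 and 31.2 in pKO, the mesenchymal cadherin Cdh2 at 50.1 against 89.3 and 146, and Fn1 at 102 against 173 and 269.6. The lateral plate and cardiac mesoderm list (5 of 7 lower, median −1.38) and the pluripotency list (14 of 19 lower, median −0.33) fell, each with a camera adjusted p of 0.0284, and adjusted p = 0.618 with an estimated correlation, with Tbx3, a member of both, at 1.27 CPM in pInv against 6.21 and 6.57. Ribosomal protein genes rose (43 of 59, median 0.16, camera adjusted p = 0.0248, and adjusted p = 0.618 with an estimated correlation). By fry, the pluripotency list alone passed (adjusted p = 0.0353).

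No gene passed for pInv against pKO in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 153 of 10265 had an unadjusted p under 0.05; DESeq2, limma-voom and limma on log2(TPM + 1) gave 0. Coprs, a cofactor of arginine methylation of histones, was at 244 CPM in pInv against 108 and 64.4 in pKO (log2 difference 1.5, SE 0.38). Ccdc7a was at 14.9 CPM in pInv against 0 and 1.64 in pKO. Zfp980 and Cox4i2 had 0 counts in pInv against 10.0 and 15.6 CPM and 5.73 and 5.74 CPM in pKO. A further copy of Ube2j2 had 10.2 CPM in pInv and 0 counts in the other 6 libraries. Without pKO2 no list passed (smallest camera adjusted p = 0.0653) and 7 genes did, and without pKO1 2 genes and 5 lists did, with nascent mesoderm (camera, adjusted p = 0.0063) and p53 targets (0.0344) among them and the pluripotency list (0.0781) not. Without WT1 or without WT2, 8 lists passed.

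The knockdown library was set beside its control to ask what the knockdown of Meteor, whose RNA was not analysed here, does. With 1 library each there is no replicate check and no p-value. Genes of nascent mesoderm stood higher in KD. Mesp1, which marks the earliest mesoderm, was at 243 CPM in KD and 71.6 in Ctrl, a ratio of 3.40 with an exact 95% counting interval of 2.82 to 4.12. Mesp2 had 34.2 against 5.08 CPM, Wnt5a 28.2 against 5.08, Fgf3 21.7 against 4.06 and Lhx1 1138 against 492. The 19 tested members of the nascent and paraxial mesoderm list had a median log2 ratio of 1.52, above all 10000 random lists matched on expression, whose central 95% ran from −0.24 to 0.46. The vascular receptor gene Kdr stood at 119.6 against 18.3 CPM (ratio 6.54, interval 4.61 to 9.55), Fn1 at 592 against 129 (4.58, 4.00 to 5.26) and Vim at 64.7 against 22.8. BMP targets had a median log2 ratio of 1.33 (percentile 100 of the random lists), with Id3 at 21.7 against 5.58 CPM and Id1 at 46.2 against 17.8, while its member Smad7 was lower, at 12.9 against 34.5. The pluripotency list had a median of −0.32 (percentile 0.43), with Sox2 at 47.6 against 118 CPM and Dppa4 at 15.7 against 40.6. With WT1 in place of Ctrl, a choice made after the data were seen, the median was 1.08 for nascent mesoderm, 0.57 for BMP targets and −0.005 for the pluripotency list, and against WT2 the pluripotency list stood at −0.33, so that value depends on the control. The primitive streak list had a median of 0.22 (percentile 99.92), with T at 358 against 340.1 CPM. The extraembryonic endoderm list (median 0.59, percentile 99.02) and the epithelial-mesenchymal transition list (0.55, percentile 99.83) also stood high. Only part of these lists reached 20 CPM in KD or Ctrl, 5 of 19 members for extraembryonic endoderm and 6 of 11 for the transition list. For nascent mesoderm and for pluripotency, 9 of 19 and 8 of 19 did. Of the 5 extraembryonic endoderm members, 1 was 2-fold higher in KD (Apoe), and of the 6 transition members, 2 were (Fn1 and Vim). Genes known from macrophages were also higher in KD (below), and whether such RNA moved these lists was not tested. Between WT1 and WT2, libraries of 1 group, the nascent mesoderm list differed by more, with a median of −1.79 (percentile 0). So did BMP targets (−1.37, percentile 0.25), primitive streak (−1.58, percentile 0) and the transition list (−0.76, percentile 0.94). Extraembryonic endoderm (−0.15) and pluripotency (0.20) differed by less. Between pKO1 and pKO2 the medians of nascent mesoderm and BMP targets were 0.43 and −0.30. Percentiles this extreme thus also arose between libraries of 1 group.

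By the size rule, 255 of 5083 genes at 20 CPM or more differed 2-fold between KD and Ctrl, 200 of them higher in KD. The same rule gave 832 genes between WT1 and WT2 and 255 between pKO1 and pKO2, libraries of 1 group each. Genes known from macrophages led the list. Lyz2, the lysozyme of macrophages, was at 175 CPM in KD and at most 0.75 in the other 6 libraries, with 379 counts in KD and 1 in Ctrl. Gpnmb had 72.0 CPM in KD and 0 counts in the other 6, at least 47.3-fold over Ctrl. Adam8 was at least 41.2-fold and Mpeg1 at least 30.9-fold higher, taking 3 counts as the floor of Ctrl. The protease Ctss had 66.95 CPM against 0.51, and Abat, an enzyme of GABA breakdown, 81.3 against 0.51. Best1 had 405 CPM against 5.58, Ccdc152 58.2 against 0 counts, and Rmc1 29.55 against 0 counts. These 3 genes are uncertain because they adjoin or overlap Fth1, Selenop and Npc1 and the strand setting of the counting is not given in the sources used here.

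Lower in KD were Chrng, a subunit of the acetylcholine receptor, at 5.08 CPM against 21.3, Hspb11 at 5.54 against 21.3, Cntn2 at 6.93 against 23.9 and Isg20l2 at 11.5 against 36.0. Relt, a receptor of the TNF family, had 6.46 CPM against 20.3, Dnmt3l, a cofactor of DNA methylation, 8.31 against 25.4, and the desmosome gene Pkp2 12.0 against 33.5. Spin2d was at 27.7 CPM against 116. Gstp1 and Gstp2, near-identical neighbours, went opposite ways, Gstp1 with 82 counts in KD and 0 in Ctrl and Gstp2 with 9 and 96, and are uncertain, as the counting divides reads between such genes. A further copy of the histone gene H2ac23 had 374 CPM against 2077, and between 3.60 and 436 in the other 5 libraries.

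**Figure D3:**
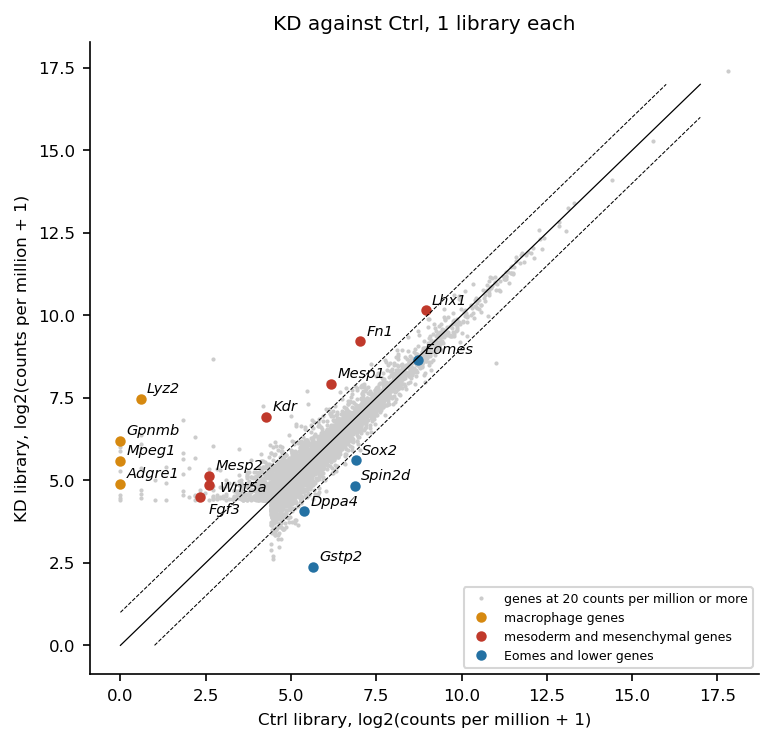
Level in the KD library (vertical axis) against the Ctrl library (horizontal axis), both as log2(CPM + 1), for genes at 20 CPM or more in either library, 1 point per gene; the solid line marks equality and the dashed lines 2-fold differences. Lyz2, Gpnmb, Mpeg1 and Adgre1 (orange) lie at the left edge, with 0 or 1 counts in Ctrl, and Mesp1 and Kdr (red) lie above the upper dashed line.

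Across 10265 genes, the log2 differences of pKO and pInv, which share the WT libraries as controls, correlated with Pearson's r = 0.459 and Spearman's rho = 0.44. Genes are not independent replicates, and groups simulated without any change against the same controls gave r = 0.418. The covariance was 0.114, against 0.133 in the simulation. With WT1 as the control of pKO and WT2 as that of pInv r was −0.209, and the reverse gave −0.174. The KD to Ctrl ratios correlated with those of pKO at r = 0.133 (rho = 0.174) and with those of pInv at r = 0.075 (rho = 0.121). Without WT2 these became −0.058 and −0.078. As no gene passed the threshold in pKO or pInv against WT, there was no overlap of called genes to count.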

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

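The comparisons in this part were chosen after the results were seen. Spin2d was higher in both libraries titled pKO than in both titled WT, by 1.41 on the log2 scale, and lower in KD than in Ctrl, at a log2 ratio of −2.03. C7 was higher in both libraries titled pKO than in both titled WT, by 1.01, and lower in KD than in Ctrl, at a log2 ratio of −1.13, on 8 counts in KD and 18 in Ctrl. Both stand out because pKO and KD moved opposite ways from their own controls in every library. The difference between the perturbations was not tested. The controls differed as well, as Ctrl stood above both libraries titled WT in both genes. In Spin2d, Ctrl was at 116 CPM, near the libraries titled pKO (123 and 99.3). Opposite responses therefore cannot be told apart from a difference between the controls. Spin2d also has close relatives whose reads the counting could split.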

How the results depend on the processing

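The fits without the 45S feature and KD against WT1 were chosen after seeing the data. Of the main results' values under alternatives 108 kept their direction, side of the threshold or size, and so did 383 values of named genes, while 28 and 9 moved, 15 and 14 turned direction and, of named genes, 4 passed the threshold. Counts of genes and lists were compared by size alone (within 1.5-fold), so a count that was kept can hold other members or directions. Where a value changed, the cause was not tested unless stated. With an estimated inter-gene correlation 0 lists passed in each of pKO against WT, pInv against WT and pInv against pKO. Without a filter on low counts, 9, 6 and 8 genes and 3, 1 and 0 lists passed. The lists were extraembryonic endoderm, epithelial-mesenchymal transition and hypoxia and glycolysis for pKO against WT, and ribosomal proteins for pInv against WT. The pluripotency list for pKO against WT, and the hypoxia and p53 lists for pInv against WT, then did not pass. Leaving out 1 library at a time gave 0 to 7 genes for pKO against WT and for pInv against pKO, and 2 to 11 and 0 to 8 lists. The log2 difference of Eomes then ranged from −0.209 to 0.327 for pKO against WT, from −0.238 to 0.32 for pInv against WT and from −0.214 to 0.206 for pInv against pKO. Its sign for pInv against WT, near 0 in the report, turned with a stricter filter (−0.007), without the 45S feature (−0.006) and with only WT, pKO and pInv in the fit (−0.001), and for pInv against pKO with limma-voom (0.009).

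With groups from the genotype field, 0, 7 and 0 genes and 6, 0 and 2 lists passed in those 3 comparisons, since that grouping exchanges libraries between the arms. Eomes was then at −0.114 for pKO against WT and −0.307 for pInv against WT. For pKO against WT the field gave Spin2d −1.216, 2210408I21Rik −1.493, Ahnak −1.676, Rian −0.874 and Spink1 −1.714. For pInv against WT it gave the Srp54c copy 0.558, Cox4i2 0.971, C7 −0.808 and Tex15 −0.306, and for pInv against pKO Cox4i2 0.001, Ccdc7a −6.561, the Ube2j2 copy 0 and Zfp980 0.126. A minimum of 10 CPM gave 613 genes for KD against Ctrl and a minimum of 50 gave 73, as more or fewer genes were tested. The H2ac23 copy had a log2 ratio of 1.441 in KD with WT1 as control. Over genes at 20 CPM or more, the KD ratios correlated with pKO at 0.273 and with pInv at 0.228. Leaving out 1 library moved the correlation of pKO with pInv to between 0.238 and 0.778, and those with KD to between −0.058 and 0.194 for pKO and between −0.078 and 0.155 for pInv. Separate WT controls gave −0.209 and −0.174.

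With the replicate number of WT and pKO as a block, 0 genes and 14 lists passed, and Eomes was at 0.038. The WT1 to WT2 and pKO1 to pKO2 differences correlated at 0.496 across genes. With 2 pairs sharing only a number, this is no pairing that the labels state. Parting these libraries by number separated 1472 genes (unadjusted p under 0.05 in edgeR's quasi-likelihood test, no overlap), against 100 by title. The main fit has no block, so its spread includes this difference, which can raise the p-values for pKO against WT. No paired analysis was possible for pInv and KD because they carry a single library. Depth limits genes under about 20 CPM, where few reads per library set the ratio.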

Other observations

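The tests of explanations in this part were chosen after the results were seen, and so were the macrophage and embryonic blood gene lists. The library titled pInv had the highest level of the epithelial cadherin Cdh1, at 1372 CPM against 475 to 827 in the other 6, with an unadjusted p of 0.00899 against WT in edgeR's quasi-likelihood test and an adjusted p of 1. It had 4.67 CPM of the phosphatase gene Dusp5, where the others held 11.2 to 20.3. In KD against Ctrl, imprinted genes had a median log2 ratio of 0.31 (percentile 98.96 of 10000 random lists), with Peg3 at 229 CPM against 132. Members of the NODAL list went both ways around a median of −0.18 (percentile 10.96). Its ligand Nodal stood at 42.5 against 81.2 CPM, Lefty1 at 10.6 against 26.9 and Smad7 at 12.9 against 34.5, while Lefty2 stood at 230.4 against 117. The blood and endothelium list had a median of 0.76, which became 0.09 with its 2 members at 0 counts in 1 of the libraries set to their bound.

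In WT2, the 38 tested members of the primitive streak and nascent mesoderm lists had a median log2 ratio to WT1 of −1.46. Removing the trend with GC content of the last 500 bases left −1.41, and the 28 members with whole-number counts in every library (within 0.005) gave −1.58, which argues against GC content and against reads shared between near-identical genes. For the mesendoderm part, an earlier stage or fewer mesendoderm cells stays open, since its median, at percentile 0 of the random lists, was taken over 2 of the lists, picked out after they were seen to be low, and gives no support. Whether such a cause explains the whole pattern was not decided. Over 59 ribosomal protein genes, log2 WT2 to WT1 ratios had an SD of 0.769, against at most 0.458 between any libraries without WT2. WT2 was picked out for its wide ratios over all genes (SD 0.795 to WT1), so a wide SD here followed largely from that choice. The value shows only that the difference was not confined to mesendoderm genes. WT1 and WT2 are 1 group, so no biological explanation from the design was tested.

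Of 30 listed macrophage genes, 23 reached 3 counts in KD and 0 in Ctrl. In KD, 14 of the 30 were at least 4-fold above the highest other library (floor of 3 counts). These 14 are 1 short of the 15 set, after the data were seen, for macrophage RNA or cells in the KD library. The floor, 1.80 CPM in the smallest library (WT2), kept genes that were low in KD from reaching 4-fold. Itgam (3.69 CPM in KD) and Cybb (4.62), with 0 counts in every other library, could not pass for that reason. The shortfall therefore does not speak against macrophage RNA or cells, and that explanation stays open. Lyz2 (175 CPM), Gpnmb (72.0) and Adgre1 (28.6) were present in KD, while Fcer1g, C1qa, Cd52 and Aif1, also abundant in macrophages, had 0 counts. Blood formation within the embryoid bodies stays open, as 1 of 15 embryonic blood genes (Lmo2, 17.1 CPM) reached that 4-fold level but 2 of the 15 reached 20 CPM in either library. Embryonic fibroblast feeder cells stay open as well, as 1 of the 9 feeder genes behind their median log2 ratio of 0.051 reached 20 CPM. The knockdown itself stays open as an untested biological explanation.

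The conflict between titles and genotype field raises the possibility that the field gives the genotypes. Of the 106 genes with an unadjusted p under 0.05 for pKO against WT, 100 had libraries that did not overlap (chance gives 33.3% of genes not selected by p), and at these Ctrl lay nearer to the libraries titled pKO at 73%, KD at 72% and pInv at 56%. Under the titles Ctrl would be expected nearer to WT and KD nearer to pKO. By the limit set first this share would have favored the field, but of the 2 other partings of these libraries, added after the 73% was seen, 1 lay slightly farther from an even split (Ctrl nearer to WT2 and pKO2 at 25.3% of 1472 genes) and 1 nearer to it (to WT2 and pKO1 at 34.5% of 142). The parting of WT1 and pKO1 from WT2 and pKO2 separated far more genes than the titles did, so it is no measure of chance. Without such a measure, the test leaves open whether the titles or the field may be right.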
